A study of Halobacterium salinarum NRC-1 with 32 samples.

How the data were processed

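RNA was measured from Halobacterium salinarum NRC-1, an archaeon of salt-saturated waters, on 2-colour spotted arrays. Per the labels, 8 RNA samples came from cells exposed to 50 mM hydrogen peroxide (H2O2) for 30 min and then moved to fresh medium, and 8 came from mock-treated control cells. Each condition was sampled at 0, 10, 20, 30, 40, 50, 60 and 120 min after the exposure. Every sample was hybridised on 2 arrays with the dyes exchanged, each time against 1 standard reference RNA from cells in mid-log growth, which gives 32 arrays. The source field of the H2O2 samples names another agent, EMS, while their descriptions and the series title name H2O2, and the descriptions were followed. The shorter-wavelength dye is given as Alexa 532 for the control arrays and Alexa 547 for the H2O2 arrays in the labels, and as Alexa 546 in the headers of all arrays.

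The deposited scanner tables give, per the file headers, the mean intensity of each spot and the mean and median intensity of its local background in both dyes, at a high and a low scanner gain, with no normalization. The image software is not given in the sources used here. Each array held 10752 spots, 4 for each of 2688 features. Gene symbols were given for 532 spots, which are 133 genes, and the other 2555 features carried no name and are counted here without one. No genome coordinates were used. The deposited value table of the series holds log10 values. Set against the scanner values, they were log10 of the shorter-wavelength over the longer-wavelength spot mean, without background subtraction and plus a constant per array, for a median of 95.9% of the spots of an array at a tolerance of 0.001. They were not turned for the dye exchange. The correlation of a column with its own array was 0.323 at the lowest, with a median of 0.991 and 2 arrays under 0.9. Column medians ran from -0.065 to 0.193. Scale and direction are thereby settled for most spots of each array except the H2O2 array at 30 min with the sample in the shorter-wavelength dye. The origin of the constant, and so the centring, stays unknown.

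In R 4.3.3 with limma 3.58.1 and statmod 1.5.0, high-gain spot means were corrected with the local background median by normexp with an offset of 50, and log2 ratios were normalized within each array by loess. Ratios were turned to sample over reference, the 4 spots of a feature were averaged, and the 2 arrays of a sample were averaged to 1 value, so that a dye exchange counts as 1 replicate. Arrays of 1 dye orientation correlated with each other between 0.092 and 0.798, which a dye bias shared by all arrays would also give, so this does not show that every array is turned the right way. Tests used lmFit and eBayes with the time as an 8-level block and Benjamini-Hochberg adjustment at 0.05. The comparisons were H2O2 against control over the 8 times, within 0 to 30 min and within 40 to 120 min, the difference between those windows, and the control samples of the late against the early window, which had no time term. With 1 RNA sample per condition and time, no test was made at a single time. The labels name no separate cultures, so p-values measure the spread between these samples and times, which may be partly technical.

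The comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes were, over 8 times, the 12 largest increases and 12 largest decreases past the threshold with the same sign at 7 or more times. In each window they were the 8 largest each way with the same sign at all 4 times. For the difference and the control comparison, where none passed in a direction, they were the 5 lowest p-values each way. Up to 4 changed members of each list were added. Of 21 gene lists, matched by symbol, 6 had no named gene on the array, 6 had 1 or 2 and were described but not tested, and 9 were tested with camera at a preset correlation of 0.01. Testing the lists among the named genes, rather than against all features, was not part of that earlier plan; it was settled before any list result was seen. The gene glmS matched the pattern for aminoacyl-tRNA synthetases and was left out of that list after the symbols were seen, since it is not one.

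The calculations were tested on simulated data with 50 features changed at each of 4 sizes among 2688. Of 50 features changed 2-fold, 50 were called over 8 times, 44 in the early window, 47 in the late window, 37 for the difference and 39 for the control comparison. For 1.5-fold changes the counts were 37, 30, 28, 11 and 13, and false calls numbered 5 to 9. A simulated list of 4 raised genes was called with an adjusted p of 0.0012 and an unchanged list of 5 had 0.748. The simulation changed 200 features, with noise independent between features and arrays. It held no offset between array series, and both conditions shared the same time effects. The real data need not meet these settings, so the counts test the calculations only and do not give the power or false calls reached here.

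Signal differed between the conditions. The median background of the shorter-wavelength dye was 759 to 1690 on control arrays and 18 to 595 on H2O2 arrays. Between 49.3% and 73.6% of the spots of a control array, and between 47% and 80.2% of those of an H2O2 array, were above their mean local background in both dyes. Of the 133 named genes, 108 in control and 120 in H2O2 samples were above background on most spots. Their array numbers put the arrays in 5 series, each holding 1 condition, with 3 for the control and 2 for the H2O2 arrays. They also nearly follow the windows, changing at 0 min and between 40 and 50 min in the controls and at 30 min in H2O2 samples; a fit of the 32 single arrays with the series as a random block is given beside the results. Since each series holds 1 condition and the block correlations were -0.033 to -0.077, that fit cannot take out an offset between series. The number of arrays limits the precision of all values.

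Alternatives were no background correction, plain subtraction, median centring, loess followed by scaling between arrays, the deposited log10 values, a filter on dim features, each dye orientation alone, each time left out, no time block, a robust prior, single arrays with the sample or the array series as a random block, the sample channel alone, other windows and other list tests. Added after the data were seen were the background mean, a fit without 0 and 30 min, list tests against all features, glmS kept, a linear trend over the time order, the low-gain scan for spots above 30000, and only features with a mean log2 intensity above 10. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.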

Results

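The response of Halobacterium salinarum NRC-1 to H2O2, an oxidant that damages DNA, proteins and iron centres, was followed for 120 min after a 30 min exposure to 50 mM. There were 8 H2O2 samples and 8 mock-treated control samples, 1 of each at every time, and each value below is the mean of 2 dye-exchanged arrays relative to 1 reference RNA. Median spot intensities in the longer-wavelength dye were 804 to 2011 on control arrays and 466 to 1490 on H2O2 arrays. Log2 differences are H2O2 minus control, with the standard error (SE). This SE is the moderated one from eBayes. Its spread comes from all samples of both conditions, also for a single window and for the control comparison, and is drawn towards that of the other features. The n beside an SE counts the times or samples averaged, so the SE is not the spread of those alone.

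Over the 8 times, phoU, a regulator of phosphate uptake, fell by 1.34 ± 0.13 on the log2 scale (SE, n = 8 times, adjusted p = 1.27e-05), a 2.54-fold decrease seen at 8 of 8 times. The gene glyA, for serine hydroxymethyltransferase, fell by 1.02 ± 0.11 (adjusted p = 2.03e-05), and serS, for seryl-tRNA synthetase, fell by 0.99 ± 0.09 (adjusted p = 8.29e-06). Both subunits of succinyl-CoA synthetase, an enzyme of the citric acid cycle, were lower, sucC at -0.94 ± 0.10 and sucD at -0.89 ± 0.10. The gene dpsA, for a ferritin-like protein that binds iron and protects DNA, rose 2.12-fold (log2 1.08 ± 0.13, adjusted p = 4.15e-05), at 8 of 8 times. In the deposited values its difference was 0.25 and no longer passed.

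Other decreases were rpl12p, for a ribosomal protein (-1.04), speB, for agmatinase (-0.86), rpmC (-0.83), the chaperone gene dnaK (-0.80), hisF of histidine synthesis (-0.78), pyrF of pyrimidine synthesis (-0.73) and cmk, for cytidylate kinase (-0.72). Other increases were cbiQ (0.81), bat, an activator of bacterio-opsin expression (0.75), the thiamine synthesis genes thiD (0.68) and thiC (0.56), purE of purine synthesis (0.65, and 0.19 in the deposited values, not past there), ndk, for nucleoside diphosphate kinase (0.56), carA (0.50), ppsA, for phosphoenolpyruvate synthase (0.50), cbiG (0.45) and argH of arginine synthesis (0.45). Another thi gene, thiL, went the other way, at -0.52. The increases depended on the scaling. Of the 24 named genes that were higher, 16 were higher under median centring and 10 in the deposited values, where thiD, thiC, ndk, carA, ppsA, cbiG and argH had negative differences and cbiQ had none (adjusted p = 0.997). Of these, ndk, ppsA and cbiG passed as decreases there (adjusted p = 0.00163 to 0.00375). Of the 40 that were lower, 39 and 36 stayed lower. Both scalings moved the named genes down as a group, from a median of -0.063 to -0.187 and -0.212. Such a shift keeps decreases negative and turns small increases, so these counts do not show that the decreases are the firmer calls. Control spots of bat were above background in 10.9% of cases against 54.7% in H2O2 samples, so its size is not exact in any comparison, and its difference was 0.23, not past the threshold, with the sample in the longer-wavelength dye alone and 0.37, also not past it, after plain background subtraction. The S-layer glycoprotein gene csg was near saturation in both dyes on 30 of the 32 arrays, so no fold is given. Its measured difference was 1.09 at high gain, 0.52 with the low-gain scan and -0.47 in the deposited values, and its direction is unsettled.

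Across all features, 1094 of 2688 passed adjusted p 0.05 in limma, 555 higher and 539 lower, among them 64 of the 133 named genes (24 higher, 40 lower; 69 adjusted over the named genes alone). With the array series as a random block the count was 888, with 364 higher. It was 677 after plain background subtraction, 1711 under median centring and 1635 in the deposited values (931 higher), of which 539 were also among the 1094. With the sample in the shorter-wavelength dye alone it was 613 and in the longer-wavelength dye alone 1390. Dim features carry part of this count. Of the 571 changed features with a mean log2 intensity above 10, 561 had the same sign in both dye orientations, against 334 of the 523 dimmer ones. Of the 64 changed named genes, 62 had the same sign in both.

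**Figure D1:**
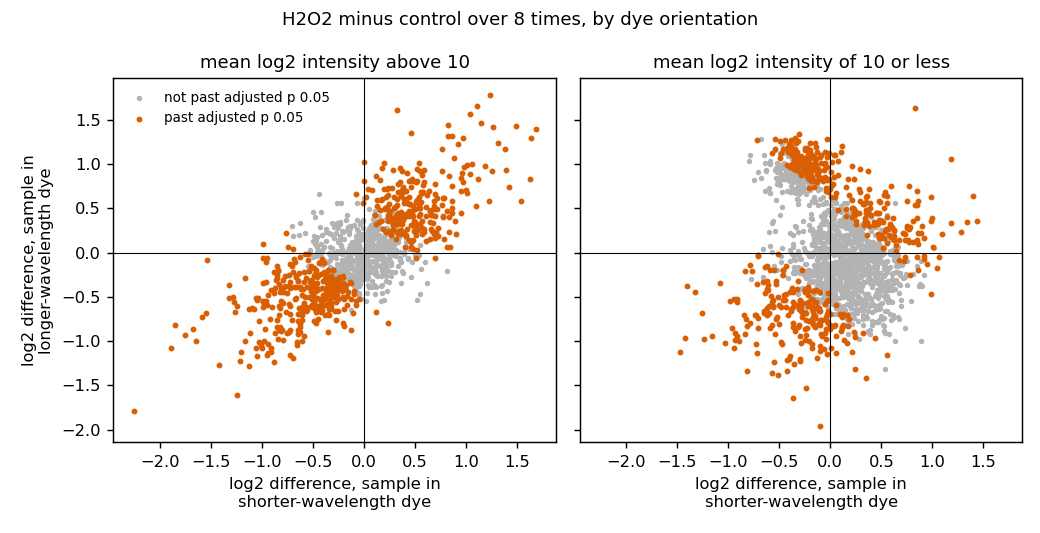
Log2 difference, H2O2 minus control over 8 times, for each feature from arrays with the sample in the shorter-wavelength dye (x axis) and in the longer-wavelength dye (y axis), in features above and at or below a mean log2 intensity of 10. Orange points passed adjusted p 0.05; the brighter features lie along the diagonal (r = 0.754 across features), while the dimmer ones do not (r = -0.143).

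**Figure D2:**
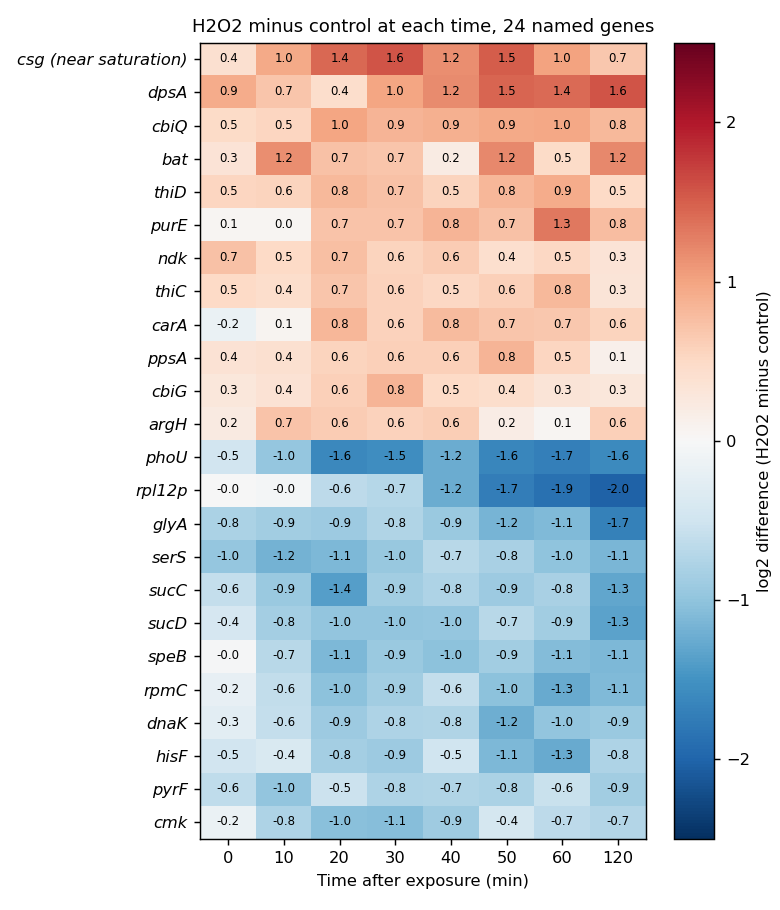
Log2 difference, H2O2 minus control, at each time after exposure in minutes for the 12 named genes with the largest increases and the 12 with the largest decreases; each cell is 1 H2O2 sample minus 1 control sample. The rpl12p cells go from -0.01 at 0 min to -2.03 at 120 min, csg is near saturation with no settled direction, and thiD, thiC, ndk, carA, ppsA, cbiG and argH turn negative over the 8 times in the deposited values.

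By fixed list over 8 times, 5 of 12 aminoacyl-tRNA synthetase genes fell, 1 rose and 6 did not pass (7 changed when adjusted over the list alone). Besides serS, lysS was at -0.68 and glyS at -0.42, the latter with spots close to background and a sign that turned under plain subtraction and in the deposited values. Of 7 central carbon genes, 3 fell (sucC, sucD and the enolase gene eno at -0.52), 1 rose (ppsA, not under median centring) and 3 did not pass, with 4 changed over the list alone. Of 5 chaperone and proteolysis genes, dnaK and the proteasome gene psmB (-0.47) fell, pan1 (0.43) and psmA (0.34) rose and 1 did not pass, with 4 over the list alone; pan1 was above background on 23.4% of control spots against 78.1% in H2O2 samples, so its size is not exact. Under median centring psmA was at -0.18, and in the deposited values it passed as a decrease, at -0.46 (adjusted p = 0.000844). Of the 5 genes matched by symbol to the DNA repair list 1 fell, endA at -0.60, and 4 did not pass (1 over the list alone). The symbol alone put endA on this list, and a role in DNA repair was not checked. In the deposited values endA was at -0.16. Its call was lost there and with the sample in the shorter-wavelength dye alone (adjusted p up to 0.209, range from 0.000851). Of 4 replication genes 1 fell, orc8 at -0.72, and 3 did not pass (1 over the list alone). Of 11 motility and taxis genes, cheY (-0.48) and cheA (-0.36) fell and 9 did not pass (2 over the list alone).

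Of 4 bacteriorhodopsin and carotenoid genes, bat, sop1 (0.45) and sop2 (0.25) rose and hop, at 0.20, did not pass (3 over the list alone); sop2 was at -0.02 in the deposited values, and sop1 was at 0.14 with the sample in the longer-wavelength dye alone and also lost its call after plain subtraction and with the array series as a block (adjusted p up to 0.403; range from 2.69e-05). The sop genes encode sensory rhodopsins. No gene for bacterio-opsin itself or for carotenoid synthesis was among the named genes of this list. Of 4 cobalamin synthesis genes, cbiQ and cbiG rose and 2 did not pass (2 over the list alone); the list's median of 0.35 turned to -0.06 under median centring and -0.25 in the deposited values. Of 12 purine and pyrimidine genes, 3 rose, pyrF fell and 8 did not pass (4 over the list alone), and the median of -0.10 went with an upward camera direction. No list of the 9 passed in camera (unadjusted p under 0.05 in 2; adjusted p = 0.0592 to 0.93), while fry, which does not compare a list with other genes, called 4. List medians with the array series as a block ran from -0.19 for central carbon to 0.35 for cobalamin synthesis. Lists with 1 or 2 named genes were not tested. There msrA, a methionine sulfoxide reductase, was at 0.23 (adjusted p = 0.0828) beside dpsA, and the succinate dehydrogenase gene sdhC fell by 0.37 while nuoL was at -0.06. The arginine deiminase gene arcA fell by 0.35, and arcC was at -0.06. With 1 time left out, arcA no longer passed without 10, 20, 30 or 50 min (adjusted p = 0.0508 to 0.0796), psmA without 20 min (adjusted p = 0.0516), and sop2 without 20, 30, 40, 50, 60 or 120 min (adjusted p = 0.0503 to 0.0849).

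In the first window, 0 to 30 min, the largest decreases were phoU at -1.15 ± 0.18 (SE, n = 4 times, adjusted p = 0.0015), serS at -1.06 ± 0.12 and sucC at -0.94 ± 0.15. The decreases of glyA (-0.83), sucD (-0.81), cmk (-0.76), pyrF (-0.73) and purL of purine synthesis (-0.73) also passed. The molybdenum cofactor gene moaC rose 1.79-fold (log2 0.84 ± 0.13, adjusted p = 0.0015), and dpsA rose 1.69-fold (0.76 ± 0.13, adjusted p = 0.00241) with a difference of -0.02 in the deposited values. The deposited values of this window include the 2 H2O2 arrays with a correlation under 0.9 to their own scan. Increases also passed for bat (with control spots mostly at background), cbiQ (0.71, at -0.02 in the deposited values), thiD (0.66, at -0.10), ndk (0.63, at -0.15) and hisA (0.62), whose control spots were above background in 34.4% of cases. With 1 time left out, hisA (adjusted p = 0.0541 to 0.126) and bat (adjusted p = 0.0552 to 0.0841) no longer passed without 10, 20 or 30 min, bat also not with the array series as a block, after plain subtraction or with the sample in the longer-wavelength dye alone (adjusted p = 0.0594, 0.478 and 0.392; range 1.46e-05 to 0.478 over all alternatives), and purL without 0, 10 or 20 min (adjusted p = 0.0584 to 0.0797). Among purine and pyrimidine genes 6 of 12 fell and none rose, and the list did not pass (camera adjusted p = 0.891). Adjusted over the list alone 8 changed. The other 6 members had positive differences, so these 8 include increases.

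In this window 533 features passed in limma, 242 higher and 291 lower, with 40 named genes (13 higher, 27 lower; 43 adjusted over the named genes alone). No list passed in camera, with none at an unadjusted p under 0.05, and 4 in fry. The count was 660 with the array series as a random block, 218 after plain subtraction, 1237 under median centring and 1211 in the deposited values, of which 690 were higher. It was 270 without 10 min, 225 without 20 min, 226 without 30 min, and 165 without 0 and 30 min, the times at which 1 condition had its arrays in different series.

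In the second window, 40 to 120 min, rpl12p fell by 1.72 ± 0.16 (SE, n = 4 times, adjusted p = 7.65e-05), a 3.29-fold decrease, and phoU fell by 1.54 ± 0.18 (adjusted p = 0.00011). The gene dpsA rose 2.64-fold (log2 1.40 ± 0.13, adjusted p = 7.62e-05) and was at 0.51 in the deposited values, still past the threshold. Decreases of glyA (-1.22), speB (-1.03), rpmC (-0.99), sucD (-0.97), dnaK (-0.97) and the translation initiation factor gene infB (-0.96) passed, as did increases of purE (0.92), cbiQ (0.90, at 0.0161 in the deposited values and not past there), bat and thiD (0.70, at -0.23 in the deposited values). With control spots mostly at background, bat was at 0.15 with the sample in the longer-wavelength dye alone (adjusted p = 0.648; range 2.02e-05 to 0.648 over all alternatives). The histidine degradation genes hutU and hutI also passed. At most 10.9% and 7.8% of their spots were above background, so they are not well above background and no fold is given.

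All 4 cobalamin synthesis genes rose in this window, cbiQ, cbiT (0.64), cobN (0.45) and cbiG (0.38), and the list passed in camera (adjusted p = 0.0252; adjusted p = 0.368 with an estimated correlation). In the deposited values its median was -0.09, cbiQ was at 0.0161 (adjusted p = 0.926), and cbiT, cobN and cbiG were at -0.04, -0.15 and -0.43. Of the 4 genes on the bacteriorhodopsin and carotenoid list (bat, hop, sop1 and sop2) 3 rose. The list passed in camera (adjusted p = 0.0499, and 0.359 with an estimated correlation). Neither passed against all features, where the adjusted p-values were 0.0583 and 0.108. With the array series as a block the medians were 0.54 and 0.45, close to the main ones by construction, since that block cannot take out an offset between conditions. The number of lists that passed was 0 without 50 min and 1 without any of 0, 30, 40, 60 or 120 min. In this window fry called 6. With 1 time left out, cbiG no longer passed without 40, 50, 60 or 120 min (adjusted p = 0.0551 to 0.0967), cbiT without 50 or 60 min (adjusted p = 0.133 and 0.0716), cobN without 50 or 60 min (adjusted p = 0.111 and 0.0798), sop1 without 40, 50 or 60 min (adjusted p = 0.0585 to 0.162) and sop2 without 40, 60 or 120 min (adjusted p = 0.0506 to 0.0802).

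In this window 878 features passed in limma, 412 higher and 466 lower, with 53 named genes (20 higher, 33 lower; 56 adjusted over the named genes alone). The count was 1027 with the array series as a block, 501 after plain subtraction, 1401 in the deposited values and 1506 under median centring, of which 874 were higher. The windows shared 340 features, 338 with the same sign, where independent lists would share 174. Among named genes 28 were shared, against 15.9.

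The difference between the windows was tested directly. It passed for rpl12p, whose effect was lower by 1.37 ± 0.23 in the late window (adjusted p = 0.0462), and for 6 unnamed features. In the control samples rpl12p went up by 0.59 between the windows and in H2O2 samples it went from -0.64 ± 0.07 to -1.41 ± 0.29 relative to the reference (SD, n = 4). The call was lost when any 1 of 0, 10, 20, 50, 60 or 120 min was left out (adjusted p = 0.0761 to 0.136), and the adjusted p ran from 1.27e-05 to 0.233 over all alternatives. For dpsA the difference was 0.64 ± 0.18 (adjusted p = 0.126), for purL 0.99 (adjusted p = 0.107), for guaB 0.59 (adjusted p = 0.161) and for cbiT 0.80 (adjusted p = 0.197), none past the threshold. The gene hutI, with spots mostly at background and so without a size given, was also higher and did not pass (adjusted p = 0.0859).

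The H2O2 arrays change series at 30 min and the control arrays between 40 and 50 min, so this difference too is nearly one between series. In total 7 features passed for the difference, 3 higher and 4 lower, against 411 at an unadjusted p under 0.05. The count was 146 with the array series as a random block over single arrays and 0 to 9 with 1 time left out, being 0 without 0, 10, 20, 50, 60 or 120 min. In the deposited values it was 17, with 4 higher, and after scaling between arrays 1.

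The control samples of 40 to 120 min were compared with those of 0 to 30 min. Control arrays up to 40 min and from 50 min on belong to different array series, so this is time together with series and not time alone. No named gene passed (1 adjusted over the named genes alone; 19 at an unadjusted p under 0.05). The lowest p-values downward were for the purine and pyrimidine genes purL at -0.90 ± 0.20 (SE, n = 4 and 4, adjusted p = 0.0637), purF at -0.76, carB at -0.55 and purM at -0.61. The histidine degradation gene hutI was also among them (adjusted p = 0.275), with spots mostly at background, so no size is given. Upward the lowest p-values were for rpl12p at 0.59 ± 0.16 (adjusted p = 0.169), rimI at 0.46, arcC at 0.64, srp19 at 0.46 and dnaK at 0.37. Without 30 min purL (-1.13), purF (-0.92), carB (-0.69), purM (-0.75), rpl12p (0.72) and arcC (0.80) did pass (adjusted p = 0.00298 to 0.0465). Of all features 5 passed in limma, 1 higher (feature_1728) and 4 lower (feature_382 and feature_543 among them, picked after their values were seen), all without a gene name, and 310 at an unadjusted p under 0.05. That count was 66 with the array series as a random block, 43 without 30 min, 0 without 10 min, and 1 to 3 without any other single time. In the deposited values it was 17, with 10 higher, and after scaling between arrays 13, with 5 higher.

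At single times there was 1 sample per condition, so the counts that follow have no replicate check. Features beyond 2-fold numbered 47 at 0 min, 80 at 10 min, 148 at 20 min, 191 at 30 min, 124 at 40 min, 244 at 50 min, 169 at 60 min and 254 at 120 min. The decreases outnumbered the increases at 7 of the 8 times, with 110 increases and 81 decreases at 30 min. Summed over the times there were 563 increases and 694 decreases, which became 1555 and 1052 under median centring and 389 and 1199 in the deposited values. Of the 389, 180 lay at 30 min, where 1 H2O2 array correlated at only 0.323 with its own scan. Beyond 2-fold in both dye orientations were 14 features at 0 min and 126 at 120 min. The spread of the differences across features was 0.41 at 0 min, against a technical spread of 0.40 from the dye exchanges, and 0.61 against 0.54 at 120 min. This technical spread also holds any dye bias of a feature that differed between control and H2O2 arrays. Such a bias cancels from the averaged differences, so the technical spread can overstate their error. Single-time differences of rpl12p were -0.01 at 0 min, -0.71 at 30 min, -1.25 at 40 min and -2.03 at 120 min, and those of dpsA were 0.92 at 0 min, 0.69 at 10 min, 0.45 at 20 min, 0.99 at 30 min, 1.18 at 40 min and 1.56 at 120 min.

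**Figure D3:**
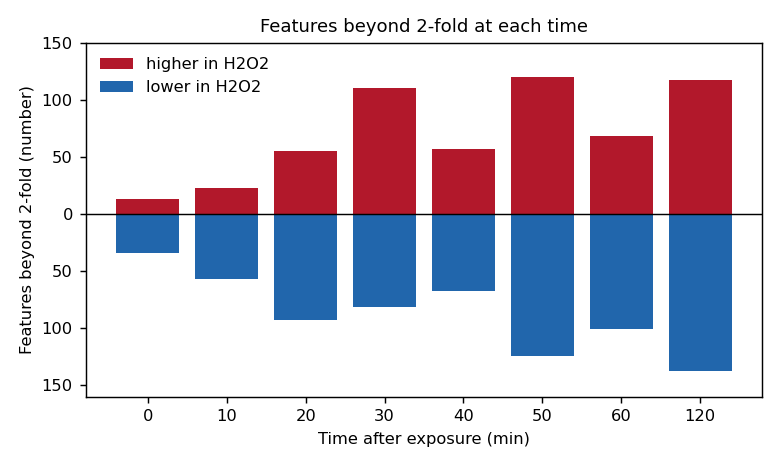
Number of features beyond 2-fold at each time after exposure in minutes, higher in H2O2 above the axis and lower below it, each from 1 H2O2 and 1 control sample without a replicate check. At 0 min 13 were higher and 34 lower, and at 120 min 117 were higher and 137 lower.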

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

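The comparison of brighter with dimmer features, the test of dyes that were not exchanged, the trend of the offset over time, the calls without 0 and 30 min and the test of rpl12p in the controls were chosen only after the results were seen; the other tests were written down before.

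That 40.7% of the features changed calls for a technical reading first, since control and H2O2 samples share no array series. With each channel normalized alone, the reference channel held a share of 0.123 of the variance of sample minus reference shifts over 8 times. Its shifts correlated at 0.009 with the differences reported here. Both values rest on how reference shifts follow the differences, so they are not separate evidence. Over 8 times they speak against a differing reference RNA as the main source of the differences. Still, the reference channel taken alone changed in 880 of all 2688 features and in 420 of the 1094 called ones. The correlation of its shifts with the differences was -0.154 at 0 to 30 min, the sign a differing reference would give, and 0.122 at 40 to 120 min. Of the 533 early calls 176 also changed in the reference channel, which changed in 770 of all 2688 features there. Differences from the 2 dye orientations correlated at 0.229 over all features, at 0.754 in the 1084 brighter and at -0.143 in the 1604 dimmer ones. An additive dye bias, also one that differed between the series, cancels from the mean of the orientations. A low correlation that comes from such a bias does not bear on the averaged calls. Whether the bias was additive in the dimmer features was not tested, and one that was not additive need not cancel. An additive bias would stay only in samples with their arrays in different series, the control at 0 min and H2O2 at 30 min. Without those times 333 of the 523 dimmer calls, a share of 0.637, passed again with the same sign, against 499 of the 571 brighter ones, in a fit that shares 6 of the 8 times. That speaks against a leftover additive bias for these 333. Why more of the dimmer calls were lost was not tested. A constant offset between the series stays open: the mean signed difference was 0.255 at 0 min and 0.541 at 120 min (rho = 0.738, exact p = 0.0458), and without the first and last time rho was 0.771 with an exact p of 0.103 at 6 times, a recheck added after the first value was seen; a rise with time also runs along the array series.

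The 2 arrays of a control sample opposed each other once turned (r = -0.48 to -0.21), while those of an H2O2 sample did not (r = 0.30 to 0.51). Had the dyes of the control arrays not been exchanged, the unturned ratios of the 2 arrays of a sample would correlate positively. In the brighter features, less the mean of each orientation, they correlated at -0.303 (range -0.664 to -0.06), the sign that exchanged dyes give. Over all features, where this test was first run, the value was 0.048 and decided nothing; the brighter features were taken after intensity limits of 10 and 11 were looked at, and a further requirement that every sample pass was tried and dropped. The dye bias of a feature correlated at 0.765 between control and H2O2 arrays. A bias shared in its pattern could exceed the small differences of control samples from the reference RNA, with a spread of 0.237 against 0.445 for the bias. In H2O2 samples the spread was 0.381 against 0.217 for the bias, so the size of the bias was not the same on all arrays.

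The effect on rpl12p differed between the windows by -1.37, the difference itself having passed the test. In H2O2 samples rpl12p changed by -0.774 between the windows and in controls by 0.593, so 0.566 of the difference lay in the H2O2 samples; the limit was 0.5, and a condition on the standard error was added after this value was seen. The smaller of the values from the 2 dye orientations was 0.668 of the larger, with the same sign, which speaks against a signal of 1 dye. The windows nearly follow the array series in both conditions, so series and time cannot be told apart in the step between windows; among H2O2 samples of the later series alone rpl12p went from -1.08 at 40 min to -1.73 at 120 min. Besides rpl12p, 6 unnamed features made up the 7 that differed between the windows.

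Regrouping the samples gave fewer calls each time. Of 100 splits of the 16 samples 1 called as many as the real one, the real split itself, with 1053 features against at most 281 in another. Among 100 splits that exchanged conditions within times it was again 1, with 1094 against 573. Of the 35 splits of each window's samples the count was 1 and 1, with 589 against 8 early and 906 against 0 late, and for the window difference and the control comparison it was 1 and 1, with 7 and 5 against 0. With conditions in separate array series, these splits do not tell treatment from series.

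In the controls cmk was -0.347 at 0 min, apart from a nearest value of 0.076 with a gap of 0.581 of the range, among 48 groups looked at.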

How the results depend on the processing

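The background mean, the low-gain scan, the intensity limit of 10, the fit without 0 and 30 min, the linear trend and list tests against all features were chosen only after results were seen. Of 3022 values for 116 gene results, 2708 kept sign and call, 223 no longer passed, 54 newly passed and 37 turned. The 2708 include genes of the window difference and the control comparison that did not pass in the main fit and stayed so. Windows that drop 30 min gave the same counts as 30 min left out, so those values enter again. Leaving out an early time does not move a late difference: late htr1 stayed at 0.4474 without 0 min. The 2708 therefore overstate how often calls held in separate tests. Over 8 times phoU ran from -1.64 to -1.07, rpl12p from -1.92 to -0.84, and dpsA from 0.25 in the deposited values to 1.26. The 1604 features at or below a mean log2 intensity of 10 are dimmer by definition, and whether signal over background limits their calls was not tested. The fits above that limit, and those with times or dim features left out, test fewer features or samples by construction; elsewhere the cause was not tested.

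Over 8 times, 677 features changed after plain subtraction, 1711 under median centring, 1635 in the deposited values, 613 and 1390 with the sample in the shorter- and the longer-wavelength dye alone, 642 above the intensity limit, and 904 to 1033 with 1 time left out. At 0 to 30 min the counts were 218 after subtraction, 1237 under median centring, 1211 in the deposited values, 233 and 866 with the sample in the shorter- and the longer-wavelength dye alone, 226 for 0 to 20 min, 165 without 0 and 30 min, and 225 to 569 with 1 time left out. At 40 to 120 min they were 501 after subtraction, 1506 under median centring, 1401 in the deposited values and 617 to 877 with 1 time left out.

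For the difference between windows, 61 passed without background correction, 0 after subtraction, 1 after scaling between arrays, 17 in the deposited values, 27 without the dimmest 25% of features, 20 and 0 with the sample in the shorter- and the longer-wavelength dye alone, 3 with a robust prior, 141 in the sample channel alone, 0 for windows split at 40 min, 2 with the low-gain scan, 54 above the intensity limit, 0 without 0 and 30 min, 17 for a linear trend, and 0 to 9 with 1 time left out. For the control comparison the counts were 14 without correction, 13 after subtraction, 13 after scaling, 17 in the deposited values, 9 without the dimmest 25% of features, 12 with the longer-wavelength dye alone, 268 in the sample channel, 0 for windows split at 40 min, 43 for 0 to 20 min, 11 with the background mean, 27 above the intensity limit, 2 without 0 and 30 min, and 0 to 43 with 1 time left out. A shift shared by both channels of an array cancels from the ratios but not from the sample channel alone. Sample and reference shifts correlated at 0.742 for the difference and 0.852 for the controls. The reference channel alone called 490 and 521 features there, so the sample-channel counts cannot be read as changes of the samples.

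Without the time block 33 features passed for the difference and 1 late list. Deviations of samples of the same time correlated between -0.02 and 0.24, above 0.1 at 3 of 8 times, which is not every pair, so the data do not show that the times pair the samples; the time block of the tests rests on the design. With single arrays and the RNA sample as a random block, 175 passed for the difference and 51 for the controls, and with the array series as a block 146 and 66, at block correlations of -0.033 to -0.077 for the series. Single arrays count each RNA sample at 2 arrays, which adds degrees of freedom.

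Of the lists over 8 times, 1 passed after subtraction, 1 under median centring, 2 in the deposited values (1 higher, 1 lower), 1 and 1 with each dye orientation alone, 4 in fry and 2 without 0 and 30 min. At 0 to 30 min 1 passed in the deposited values, central carbon and lower, and 4 in fry. At 40 to 120 min 1 passed in the deposited values, again central carbon and lower. In the higher direction 1 passed after subtraction, under median centring, after scaling, with each dye orientation alone, with the background mean, above the intensity limit and without 0 and 30 min, 0 with an estimated correlation, 0 against all features, and 0 to 2 with 1 time left out. There 6 passed in fry, 2 higher and 4 lower. Beyond 2-fold, summed over times, were 1257 features, 417 without correction, 3575 after subtraction, 2607 under median centring, 2905 and 3216 with the shorter- and the longer-wavelength dye alone, 5050 at a 1.5-fold limit, 551 in both orientations and 618 above the intensity limit.

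Among the genes named by the rule, the sign turned in the deposited values over 8 times for argH (-0.0373), carA (-0.0186), cbiG (-0.33), csg (-0.47), glyS (0.0242), ndk (-0.38), ppsA (-0.36), psmA (-0.46), sop2 (-0.0216), thiC (-0.21) and thiD (-0.17). At 0 to 30 min it turned for cbiG (-0.24), cbiQ (-0.0154), csg (-0.11), dpsA (-0.0164), glyS (0.11), ndk (-0.15), ppsA (-0.28) and thiD (-0.10), and at 40 to 120 min for cbiG (-0.43), cbiT (-0.0353), cobN (-0.15), csg (-0.82), ppsA (-0.43), sop2 (-0.0248) and thiD (-0.23). In the deposited values over 8 times cbiG, csg, ndk, ppsA and psmA passed with the turned sign (adjusted p = 0.000844 to 0.00375), and late cbiG, csg and ppsA did (adjusted p = 1.37e-05 to 0.00689). Under median centring it turned over 8 times for cbiG (-0.0193), ndk (-0.0487), ppsA (-0.0172) and psmA (-0.18), early for ppsA (-0.0343), and late for cbiG (-0.076) and ppsA (0.00). Of all 24 higher and 40 lower named genes over 8 times, 16 and 39 kept their sign under median centring and 10 and 36 in the deposited values. The median of all named genes was lower in both than in the main fit, which by itself favours kept decreases over kept increases. After subtraction glyS was at 0.0049 over 8 times and 0.0748 late, and in the sample channel alone ndk was at -0.19 over 8 times and sop2 at -0.12 late.

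Many calls of single genes were lost in 1 or more alternatives, single times left out included, and the highest adjusted p over the alternatives stands in brackets. Over 8 times these were arcA (0.161), argH (0.734), bat (0.296), carA (0.876), cbiG (0.866), cbiQ (0.997), cheA (0.179), dpsA (0.0775), endA (0.209), eno (0.0574), glyS (0.988), ndk (0.704), ppsA (0.883), psmA (0.191), purE (0.123), sdhC (0.112), sop1 (0.403), sop2 (0.843), thiC (0.463) and thiD (0.14). At 0 to 30 min they were bat (0.478), cbiG (0.833), cbiQ (0.929), cheY (0.183), csg (0.552), dnaK (0.0832), dpsA (0.931), eno (0.13), glyS (0.937), hisA (0.439), lysS (0.0684), ndk (0.585), orc8 (0.0663), pan1 (0.153), ppsA (0.854), psmB (0.0787), purL (0.0853), pyrF (0.102), sucC (0.0585) and thiD (0.529). At 40 to 120 min they were bat (0.648), carA (0.527), cbiG (0.635), cbiQ (0.926), cbiT (0.836), cheA (0.15), cheY (0.0576), cobN (0.445), csg (0.0597), cysS (0.0739), eno (0.253), glyS (0.899), htr1 (0.299), hutI (0.333), hutU (0.0968), lysS (0.163), orc8 (0.0512), ppsA (1), pyrF (0.141), sdhC (0.214), sop1 (0.693), sop2 (0.884), sucC (0.0693) and thiD (0.258).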

Other observations

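The comparison of purine and pyrimidine genes between windows was chosen only after the result was seen.

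No purine or pyrimidine gene passed for the difference between windows (lowest adjusted p = 0.107, purL), and what follows compares medians only. In controls the median change of the 12 purine and pyrimidine genes from the early to the late window was -0.189, with 9 of 12 lower, among them purL (-0.90), purF (-0.76) and purM (-0.61). In H2O2 samples the median change was 0.094, with 5 of 12 lower, and purL, purF and purM were at 0.09, -0.13 and 0.10. The lower values of purL, purF, purM and carB under H2O2 in the first 30 min could therefore rest on controls that started high, and the later absence of a difference on controls that came down. As a list the 12 genes were lower late in the controls (camera adjusted p = 0.000558; adjusted p = 0.215 with an estimated correlation), a test that was not among those fixed beforehand.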
